A study of Homo sapiens with 22 samples.

How the data were processed

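Gene expression was measured on CodeLink human whole genome arrays, which read 1 sample per array with short oligonucleotide probes. Per the labels' protocols, total RNA was reverse transcribed, biotin-labelled cRNA was made from it by in vitro transcription, and the bound target was detected with Cy5 on an arrayWoRx scanner. The 22 arrays came from 2 human tumour lines, Mia-PaCa-2 (pancreatic carcinoma) and SK-MEL-28 (melanoma). Cells were either left untreated or given Amblyomin-X, a recombinant Kunitz-type protease inhibitor of tick origin, at 1 µM for 4 h. Each line and condition had its own group, with 6 arrays per group in Mia-PaCa-2 and 5 in SK-MEL-28. Groups and replicate numbers were taken from the sample titles. In the description labels all 6 untreated Mia-PaCa-2 arrays carry the replicate number 1, whereas their titles number them 1 to 6. Each hybridization is described as an independent cRNA preparation. Whether the preparations came from separate cultures is not given in the sources used here, so p-values measure only the spread between these arrays.

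Per the file headers, the per-sample files deposited by the authors hold 1 intensity per probe on a linear scale, with no log taken. The background correction, the probe filter and the quality flags behind these intensities are not given in the sources used here. The deposited table of the whole series holds the authors' normalized intensities of the same probes, also on a linear scale. The method is not stated. Judging from the values, the normalization was a quantile normalization within each line, since every array of a line shares 1 maximum and the ranks equal those before normalization (Spearman's rho of 1 on every array). In that table the 4 lowest probes of each Mia-PaCa-2 array, the 12 lowest of each SK-MEL-28 array and between 0 and 14 of the brightest probes per array had no value. Mia-PaCa-2 had 11606 probes and SK-MEL-28 had 7975, with 5324 in both lines. Median intensities before normalization ran from 68.1 to 156 on the Mia-PaCa-2 arrays and from 55.4 to 165 on the SK-MEL-28 arrays. In SK-MEL-28 the intensities of 4 probes on untreated array 4 and of 1 probe on treated array 2 were large negative overflow values, which have no normalized value in the table. They and all other intensities at or below 0 were left out where the per-sample intensities were used. Probes were named through the platform annotation supplied with the data. Of 14257 probes in either line, 8051 had 1 gene symbol, 400 had several and 5806 were unnamed here. No genome was used, so no positions are given.

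The normalized values were put on the log2 scale and each line was fitted alone, because the lines were normalized apart. A probe was tested if it had a value on at least 3 arrays of each group. Treated and untreated arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment and a threshold of 0.05. The difference of the treatment effects between the lines was tested as a contrast over all 22 arrays on the probes tested in both lines. Levels were not tested between lines. Before the data were examined, 29 gene lists had been fixed. Lists with at least 5 measured genes were tested with camera at a preset correlation between genes of 0.01, with 1 probe per gene (the one with the highest mean level in the line). For camera, missing values were filled with the group mean (60 genes in Mia-PaCa-2 and 71 in SK-MEL-28). Each list was tested again with an estimated correlation and with fry, whose directional test asks whether a list's genes move on balance one way and whose mixed test asks whether they change in either direction. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9 prepared the tables and figures.

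The naming rule was also fixed beforehand. In each line, the 12 genes with the largest rise and the 12 with the largest fall past the threshold would be named, and where none passed, the 10 genes with the smallest p, each gene by its probe with the highest mean level. From each list up to 4 members with the smallest p could be named, and for the difference between lines the 10 genes with the smallest p. The lists whose members are named here, and how many of each, were chosen after the list results had been seen. Probes without a single gene symbol are given only as counts.

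On simulated data made from the arrays' own means and spreads, limma recovered 1.49%, 50.7% and 90.9% of genes changed by 0.5, 1 and 2 on the log2 scale in Mia-PaCa-2. In SK-MEL-28 it recovered 0%, 40.3% and 87.9%. Among the unchanged simulated probes it called 7 in Mia-PaCa-2 and 6 in SK-MEL-28. With no list shifted, camera called 0 of the 26 lists in Mia-PaCa-2 and 0 of the 20 in SK-MEL-28. With the proteasome list shifted by 0.5 it found that list in both lines, and it called 1 other list in Mia-PaCa-2 and 0 in SK-MEL-28. The simulated noise was independent between genes. On the real Mia-PaCa-2 arrays the estimated correlation was 0.305 for the G2/M and 0.385 for the DNA replication list. Other splits of those arrays gave a median of 2 lists and up to 7. The simulation therefore does not give the rate of false list calls on the real arrays. The number of arrays limits the precision. In Mia-PaCa-2 the median 95% interval of a change reached 0.51 on the log2 scale (1.43-fold) to either side, and in SK-MEL-28 it reached 0.58 (1.50-fold).

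Any 2 arrays of a line shared at most 2 identical intensities, and every array was counted as 1 replicate. Arrays of different lines were not compared for identical intensities. Whether same-numbered arrays pair was tested by correlating their deviations from the group means. In SK-MEL-28 all 5 pairs exceeded the limit of 0.1 set for pairing (0.247 to 0.602), and in Mia-PaCa-2 only 3 of 6 did (-0.187 to 0.437). The labels say nothing about shared days or batches. By the limit of 0.1 the SK-MEL-28 numbers were taken to pair the arrays. Results with the replicate number as a block are given for counts of probes, for list calls that changed and for a few genes. The SE and p of the SK-MEL-28 genes, and the choice of the genes named, come from fits without the block and may differ with it. Only 6 of the 10 SK-MEL-28 arrays correlated best with the array of their own number. The 4 brighter scans of that line are the arrays numbered 1 and 3, so pairing and brightness are not told apart. Values given without mention of the block come from fits without it.

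Alternatives planned in advance were quantile normalization or median centring of the table's values, leaving out the lowest 25% of probes by level, complete probes only, the replicate block, an intensity trend with robust settings, array weights, quantile normalization of the per-sample intensities, all 22 arrays in 1 fit, Welch's test, an estimated correlation, the mean of all probes of a gene, and each array left out in turn. After the data had been seen, fits were added without 4 arrays that resembled both lines (also with an estimated correlation and with the replicate block), with the replicate block at an estimated correlation in SK-MEL-28, with an estimated correlation for each array left out, and with the brightness of the scans. Counts of other groupings used 100 random splits of the arrays of a line.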

Results

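The arrays measured RNA from 2 human tumour cell lines, Mia-PaCa-2 from a pancreatic carcinoma and SK-MEL-28 from a melanoma, with and without 4 h of exposure to 1 µM Amblyomin-X, a recombinant tick protein of the Kunitz inhibitor family. There were 6 treated and 6 untreated arrays of Mia-PaCa-2, and 5 of each kind of SK-MEL-28. The series title places cell cycle genes and the ubiquitin-proteasome system among the targets of the inhibitor, so these gene groups were compared alongside stress, metabolic, cell death and marker genes. After the normalization by the authors, 11604 probes could be tested in Mia-PaCa-2 and 7973 in SK-MEL-28, and 5321 in both.

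The arrays of a line did not all look alike. Untreated arrays 4 and 5 of Mia-PaCa-2 and treated arrays 3 and 5 of SK-MEL-28 resembled both lines. Each array was written as a weighted sum of the mean profiles of both lines over 5195 probes, the profiles being taken from the other 18 arrays. On the other 10 Mia-PaCa-2 arrays the Mia-PaCa-2 profile had a weight of 0.95 to 1.08 and the SK-MEL-28 profile one of -0.0441 to 0.0271. On the other 8 SK-MEL-28 arrays these weights were -0.0223 to 0.0756 and 0.927 to 1.10. The weights of the Mia-PaCa-2 and SK-MEL-28 profiles were 0.632 to 0.642 and 0.590 to 0.605 on the Mia-PaCa-2 untreated pair, and 0.614 to 0.816 and 0.467 to 0.566 on the SK-MEL-28 treated pair. These 4 arrays correlated with each other across lines by 0.864 to 0.962, against 0.357 to 0.471 for the other arrays of different lines. The 4 arrays were picked out after the values had been seen. Because they lie on the untreated side in Mia-PaCa-2 and on the treated side in SK-MEL-28, values without them are given beside each gene list tested within a line and for most of the named genes.

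**Figure D1:**
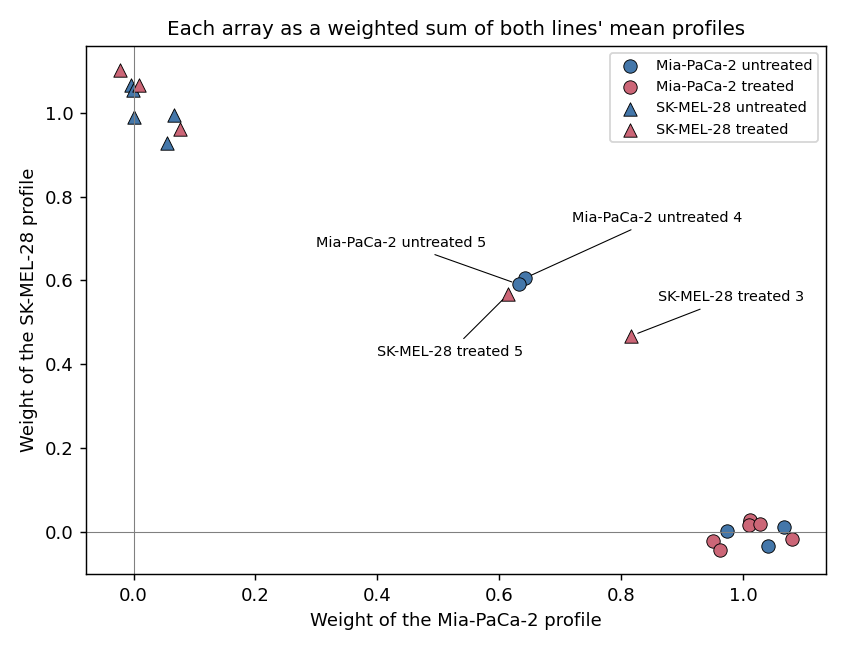
Weight of the SK-MEL-28 mean profile (vertical axis, no unit) against that of the Mia-PaCa-2 mean profile (horizontal axis, no unit) for each of the 22 arrays, with circles for Mia-PaCa-2, triangles for SK-MEL-28, blue for untreated and red for treated cells. The 4 named arrays lie at weights of 0.614 to 0.816 for Mia-PaCa-2 and 0.467 to 0.605 for SK-MEL-28, and every other array lies near 1 for its own line and near 0 for the other.

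In Mia-PaCa-2, camera with its preset correlation placed the list of G2 and M phase genes higher in treated cells and the list of glycolysis and hypoxia response genes lower, and with an estimated correlation neither passed. Of 43 measured G2/M genes 36 had a positive change, with a median of 0.35 on the log2 scale (adjusted p = 0.000210, and 0.766 with an estimated correlation), but the median was 0.13 (adjusted p = 0.0572) without untreated arrays 4 and 5. Of 13 glycolysis and hypoxia genes 8 had a negative change, with a median of -0.60 (adjusted p = 0.00194, and 0.766 with an estimated correlation), and -0.36 without those arrays (adjusted p = 0.0441, and 0.71 with an estimated correlation). Lists for DNA replication and repair (31 genes, 25 positive, median 0.34, adjusted p = 0.00743) and of oxidative phosphorylation (54 genes, 40 positive, median 0.22, adjusted p = 0.0390) also passed in the upward direction, both with an adjusted p of 0.822 at an estimated correlation, and without those arrays their medians were 0.02 (adjusted p = 0.676) and 0.05 (adjusted p = 0.345). None of these 4 calls among the 26 lists tested held with an estimated correlation between genes, and none of the 26 passed the directional test of fry. No single gene passed the threshold.

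The G2/M list holds genes that build and control the mitotic spindle and chromosome segregation. Its members with the smallest p were GTSE1, which restrains p53 in G2, at 1.09 ± 0.30 (SE; log2 change, 6 arrays per group), the cyclin-dependent kinase subunit CKS1B at 0.53 ± 0.16 (0.31 by a second probe), the microtubule depolymerase KIF2C at 1.19 ± 0.35 and the kinetochore protein CENPF at 0.80 ± 0.24. None of the 43 passed either over all probes or adjusted over the list alone (smallest value 0.0526), and 9 had an unadjusted p under 0.05 by limma. The list's median lay above the untreated mean on 6 of 6 treated arrays, and on 5 of 6 when untreated arrays 4 and 5 were left out of that mean. Without untreated arrays 4 and 5 the median was 0.13 (adjusted p = 0.0572) and 28 of 43 changes were positive. Leaving out untreated array 5 alone moved the median to 0.20 (adjusted p = 0.000370, and 0.724 with an estimated correlation), and without both arrays GTSE1 had 0.76, CKS1B 0.50, KIF2C 0.64 and CENPF 0.46.

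The members of the glycolysis and hypoxia list with the smallest p were enzymes of the lower and upper glycolytic pathway. Phosphoglycerate kinase PGK1 had a log2 change of -1.50 ± 0.40 (SE), phosphofructokinase PFKL -1.37 ± 0.39, enolase ENO2 -0.88 ± 0.26 and glyceraldehyde-3-phosphate dehydrogenase GAPDH -1.37 ± 0.44. In absolute terms GAPDH lay at 11.15 ± 0.69 (SD, n = 6) in treated and 12.52 ± 1.05 (SD, n = 6) in untreated cells on the log2 intensity scale. PFKL and ENO2 were dim, at 5.08 and 5.20 in treated and 6.45 and 6.07 in untreated cells. No member passed over all probes, 6 of 13 passed adjusted over the list alone and 7 had an unadjusted p under 0.05 by limma. The mixed test of fry, which asks for change in either direction, gave an adjusted p of 0.00600, and its directional test 0.258. All 6 treated arrays lay below the untreated mean of the list, with and without untreated arrays 4 and 5 in it. Without untreated arrays 4 and 5 the median was -0.36 (adjusted p = 0.0441, and 0.71 with an estimated correlation), and PGK1 had -1.51, PFKL -0.76, ENO2 -0.63 and GAPDH -1.10.

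The DNA replication list was led by the replicative helicase subunits MCM7 (0.70 ± 0.23, log2 change ± SE) and MCM2 (0.97 ± 0.35) and by POLA1, the catalytic subunit of DNA polymerase alpha (0.68 ± 0.26). None of its 31 genes passed over all probes or adjusted over the list alone, and 4 had an unadjusted p under 0.05 by limma. Without untreated arrays 4 and 5 the median was 0.02 (adjusted p = 0.676), with 16 genes positive and 15 negative, and MCM7 had 0.42, MCM2 0.51 and POLA1 0.37. The call also ended when untreated array 4 (median 0.14, adjusted p = 0.159), untreated array 6 (0.38, adjusted p = 0.0563) or treated array 3 (0.30, adjusted p = 0.0515) was left out alone, and with array weights (median 0.08, adjusted p = 0.213). Among the oxidative phosphorylation genes, NDUFA6 (0.74 ± 0.28) and NDUFA12 (0.52 ± 0.21), both subunits of complex I, and the cytochrome oxidase subunit COX5A (0.48 ± 0.20) had the smallest p. None of these 54 genes passed over all probes or adjusted over the list alone, and 4 had an unadjusted p under 0.05. That list's median of 0.22 lay within the range of 0.05 to 0.26 that held 95% of random lists matched on probe level, and it was 0.05 without untreated arrays 4 and 5 (adjusted p = 0.345), where NDUFA6 had 0.35, NDUFA12 0.26 and COX5A 0.27. Its call ended on leaving out untreated array 1 (median 0.19, adjusted p = 0.265), 4 (0.06, adjusted p = 0.303) or 6 (0.20, adjusted p = 0.165) or treated array 1 (0.13, adjusted p = 0.178), 3 (0.18, adjusted p = 0.152) or 5 (0.20, adjusted p = 0.0621), without the lowest 25% of probes (0.0703) and with array weights (0.512). NDUFA6 stood at 9.39 on treated array 4 and at 8.41 to 8.73 on the other treated arrays. Both lists lay above the untreated mean on 6 of 6 treated arrays, but above the mean of the other 4 untreated arrays DNA replication lay on 4 of 6 and oxidative phosphorylation on 3 of 6.

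**Figure D2:**
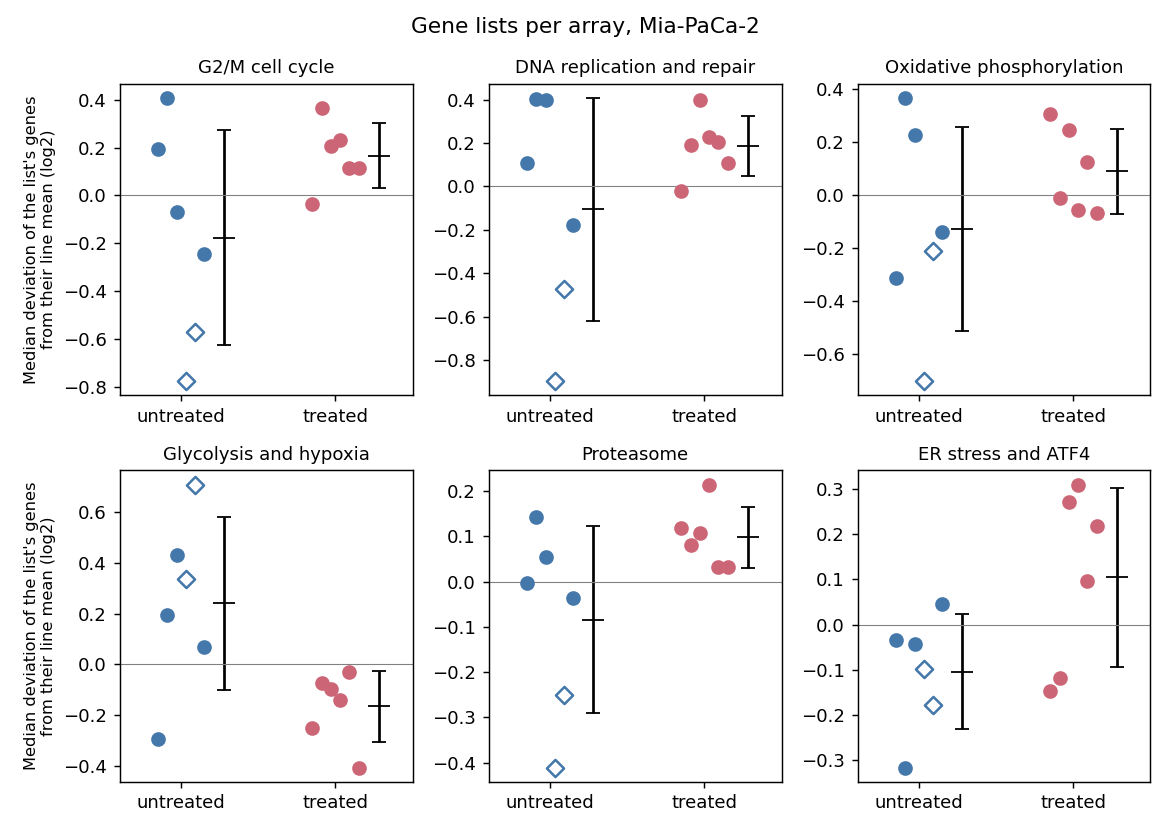
Median deviation of a list's genes from their mean over the line (vertical axis, log2) on each Mia-PaCa-2 array, untreated and treated, for 6 gene lists, with points for arrays, open diamonds for untreated arrays 4 and 5, and bars for the mean and SD of a group. For glycolysis and hypoxia the treated arrays span -0.40 to -0.03 and the untreated ones -0.29 to 0.71, and for G2/M the treated arrays span -0.04 to 0.37 and the untreated ones -0.78 to 0.41.

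The ubiquitin-proteasome lists did not pass in Mia-PaCa-2. Of 36 proteasome genes 26 had a positive change, with a median of 0.24 (adjusted p = 0.115), and the treated arrays lay above the untreated mean in 6 of 6 cases, or 4 of 6 with untreated arrays 4 and 5 left out of that mean. The members with the smallest p went both ways. Of the core particle subunits, PSMB1 had a log2 change of 0.55 ± 0.17 (SE), PSMB2 0.50 ± 0.18 and PSMB5, which carries the chymotrypsin-like activity, -0.85 ± 0.31. The ubiquitin receptor PSMD4 had 0.57 ± 0.23. By limma 9 proteasome genes had an unadjusted p under 0.05, none passed over all probes and none passed adjusted over the list alone. The list's median was 0.07 without untreated arrays 4 and 5 (adjusted p = 0.345) and 0.10 without untreated array 4 (adjusted p = 0.241), and leaving out untreated array 2 gave 0.29 with an adjusted p of 0.0321 (0.705 with an estimated correlation). PSMB1 had 0.48, PSMB2 0.32, PSMB5 -0.66 and PSMD4 0.31 without untreated arrays 4 and 5. Ubiquitin conjugation had 21 of 33 changes positive and a median of 0.11 (adjusted p = 0.629, and a median of -0.05 without those 2 arrays). It was led by the conjugating enzyme UBE2N at 0.59 ± 0.19 (0.12 by a second probe, and one treated array stood apart at 12.20 against 11.58 to 11.80), the SCF ligase adaptor SKP1 at 0.56 ± 0.22 and the mitotic conjugating enzyme UBE2C at 0.49 ± 0.21, and these had 0.41, 0.34 and 0.28 without those arrays. Deubiquitinases had 14 of 19 positive (median 0.23, adjusted p = 0.395, and -0.00 without those arrays), with USP13 at 0.57 ± 0.26 (0.17 without them) and USP47 at 0.33 ± 0.22 (0.28 without them, and 0.18 to 0.33 over the alternative fits). Adjusted over the list alone, none of the ubiquitin conjugation genes or deubiquitinases passed, as over all probes.

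Other lists fixed for the cell cycle and stress did not pass in Mia-PaCa-2 either. The G1/S list was split, with 8 genes positive and 8 negative (adjusted p = 0.406), and held lower values for the E2F partner TFDP1 (-0.59 ± 0.27, log2 change ± SE), cyclin CCND3 (-0.60 ± 0.33) and the retinoblastoma protein RB1 (-0.54 ± 0.30, 6 treated and 5 untreated arrays). Without untreated arrays 4 and 5 its median moved from 0.00 to -0.24 (adjusted p = 0.202), and TFDP1 had -0.59, CCND3 -0.28 and RB1 -0.57. Leaving out treated array 5 took RB1 to -0.31. Heat shock genes had 10 of 15 changes negative (median -0.17, adjusted p = 0.406, and -0.07 without those arrays), among them the chaperone HSPH1 at -0.69 ± 0.30 (-0.49 without them). Members of the cell death lists went both ways, with 6 of 17 positive among apoptosis-promoting genes, 4 of 9 among apoptosis-inhibiting genes and 7 of 16 among p53 targets, and 2, 1 and 0 members had an unadjusted p under 0.05 by limma. Their medians were -0.01 for apoptosis-promoting genes (adjusted p = 0.664), -0.02 for apoptosis-inhibiting genes (0.851) and -0.00 for p53 targets (0.664), and -0.03, 0.09 and -0.12 without those arrays. The G1/S median and its camera direction differ in sign, as do those of the apoptosis-inhibiting genes. None of these genes passed over all probes or adjusted over the list alone.

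Over all probes in Mia-PaCa-2, limma called 0 at an adjusted p under 0.05, and the smallest adjusted p was 0.120. At an unadjusted p under 0.05 there were 1113 probes, 602 higher and 511 lower, where chance gives 580.2. The unadjusted count was 636 without untreated arrays 4 and 5, 689 without untreated array 4, 643 without untreated array 5 and 1887 without untreated array 1.

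The 10 Mia-PaCa-2 genes with the smallest p, each read from its probe with the highest mean level, did not pass (adjusted p = 0.501 each) and were mixed in function. A probe of N4BP2L2 with a lower mean level, singled out after its values were seen, had a smaller p (-2.13 ± 0.32, limma, adjusted p = 0.120), while the other 3 probes of that gene had 0.47, 0.42 and -0.07. CHAC1, a glutathione-degrading enzyme induced through ATF4, had a log2 change of 0.93 ± 0.20 (SE), from 5.27 ± 0.39 (SD, n = 6) in untreated to 6.20 ± 0.22 (SD, n = 6) in treated cells, and it was higher on all 6 treated arrays than on any untreated one. The small GTPase RAC1 had 0.59 ± 0.15, the proton-gated channel subunit ASIC3 1.49 ± 0.36, the extracellular matrix protein gene OMD 0.96 ± 0.22 and the non-coding RNA LINC01913 0.70 ± 0.17. A second probe of RAC1 had 0.16. Lower values were found for the ceramide synthase CERS2 (-1.47 ± 0.36), LRFN4 (-1.11 ± 0.25), SIL1, the nucleotide exchange factor of the endoplasmic reticulum chaperone BiP (-1.0 ± 0.24), the membrane mucin MUC1 (-0.93 ± 0.23) and MBIP (-0.79 ± 0.21). The LRFN4 and SIL1 probes were dim, at 4.61 and 4.70 in treated and 5.72 and 5.70 in untreated cells. Without untreated arrays 4 and 5 these 10 genes kept their direction, with CHAC1 at 1.05, ASIC3 at 0.98, CERS2 at -1.13 and MBIP at -0.54. They were chosen by small p on the same arrays, so their kept direction and the separation of CHAC1 add no further support.

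In SK-MEL-28 no gene passed by limma and none of 20 gene lists passed by camera, where 2 lists had an unadjusted p under 0.05, or by fry. Cytosolic ribosomal protein genes had the smallest p among the lists, with 19 of 22 changes positive and a median of 0.63 on the log2 scale (adjusted p = 0.0521, and 0.660 with an estimated correlation), and all 11 mRNA splicing genes had positive changes (median 0.27, adjusted p = 0.0835, and 0.565 with an estimated correlation). The ribosomal list lay above the untreated mean on 3 of 5 treated arrays and the splicing list on 5 of 5, or 1 of 3 and 3 of 3 without treated arrays 3 and 5. Ribosomal protein probes measured in both lines had a median log2 level of 7.76 on the 8 SK-MEL-28 arrays that resembled their own line and 12.07 on treated arrays 3 and 5, where the medians over all probes were 7.02 and 7.16. Whether the probe names or the target hold for those 8 arrays was not settled, which limits what the gene names stand for in SK-MEL-28 and in the comparison of the lines.

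The ribosomal list passed with the replicate number as a block (adjusted p = 0.00674), and not with the block at an estimated correlation (adjusted p = 0.707). Without treated arrays 3 and 5, which resembled both lines, its median was -0.29 (adjusted p = 0.715), with 5 genes positive and 17 negative. With the block and without those arrays the median was -0.00 (adjusted p = 0.942). It passed on leaving out untreated array 1 (median 0.98, adjusted p = 0.00937) or 3 (0.95, adjusted p = 0.00643) or treated array 2 (1.07, adjusted p = 0.00197) or 4 (1.11, adjusted p = 0.00173), and in none of these fits with an estimated correlation (adjusted p = 0.669, 0.689, 0.481 and 0.613). Leaving out any of the other 6 arrays gave medians of 0.26 (without treated array 3) to 0.43, and the list did not pass. Among its members with the smallest p, RPS29 had a log2 change of -0.69 ± 0.33 (SE, 4 treated and 4 untreated arrays) and RPS24 0.29 ± 0.15. RPS16 had 2.83 ± 1.63 and RPS2 2.42 ± 1.46. On untreated array 5 RPS16 stood at 8.17, against 5.40 to 5.94 on the other untreated arrays. RPS2 stood at 13.33 and 12.71 on treated arrays 3 and 5 and at 6.41 ± 0.79 (SD, n = 8) on the other SK-MEL-28 arrays, and without those 2 arrays RPS29 had -0.39, RPS24 0.38, RPS16 -0.20 and RPS2 -0.30. None of the 22 passed over all probes or adjusted over the list alone, and 0 had an unadjusted p under 0.05. Of the splicing genes, HNRNPU had 1.18 ± 0.60, U2AF1 0.48 ± 0.31 and SRSF6 0.34 ± 0.22, with none passing over all probes or adjusted over the list alone. The splicing median was 0.10 without treated arrays 3 and 5 (adjusted p = 0.715), and HNRNPU had 0.49, U2AF1 0.10 and SRSF6 0.44. Leaving out treated array 5 alone took U2AF1 to 0.26, and leaving out untreated array 1 took SRSF6 to 0.22. Over the other alternative fits U2AF1 ran from 0.0084 to 0.78 and SRSF6 from 0.17 to 0.59. Leaving out treated array 2 took the splicing median to 0.49 with an adjusted p of 0.0320 (0.481 with an estimated correlation).

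**Figure D3:**
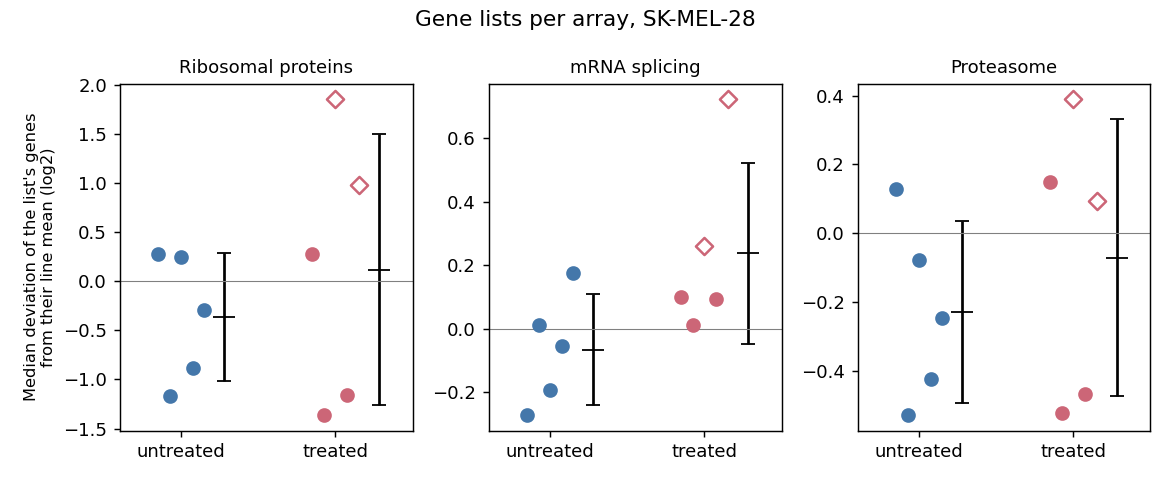
Median deviation of a list's genes from their mean over the line (vertical axis, log2) on each SK-MEL-28 array, untreated and treated, for 3 gene lists, with points for arrays, open diamonds for treated arrays 3 and 5, and bars for the mean and SD of a group. For ribosomal proteins the treated arrays span -1.36 to 1.85 and the untreated ones -1.17 to 0.27.

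The proteasome and cell cycle lists were small in SK-MEL-28. Of 11 proteasome genes 6 had positive changes (median 0.13, adjusted p = 0.593). Leaving out 1 array moved this median between -0.08 (without treated array 1) and 0.28 (without treated array 4), and the list did not pass in any of these 10 fits. PSMB2 had 0.92 ± 0.43 (log2 change ± SE), PSMA6 0.73 ± 0.38 and the regulatory particle subunit PSMD8 1.93 ± 1.06, and without treated arrays 3 and 5 these were 0.14, 0.13 and -0.07 and the list's median -0.05. Ubiquitin conjugation had 7 of 11 positive (median 0.09, adjusted p = 0.594, and -0.12 without those arrays), with UBE2N at 1.61 ± 1.05 and UBE2T at 0.98 ± 0.79, which became -0.36 and -0.03. Leaving out 1 array moved UBE2T between 0.56 (without treated array 5) and 1.73 (without treated array 1). The G2/M list was split, with 5 of 11 genes positive (median -0.01, adjusted p = 0.662), where camera gave the opposite direction, including the mitotic kinase CDK1 at 0.65 ± 0.29 and WEE1, which inhibits CDK1, at 1.15 ± 0.52. Without treated arrays 3 and 5 the G2/M median was 0.02, CDK1 had 0.28 and WEE1 0.62. Of 8 G1/S genes 6 were positive (median 0.18, adjusted p = 0.593), with cyclin CCNE1 at -0.43 ± 0.24 and the replication licensing factor CDC6 at 0.60 ± 0.39, and without those arrays the median was 0.13, CCNE1 had -0.46 and CDC6 0.24 (0.93 when treated array 1 alone was left out). Over the alternative fits CCNE1 ran from -0.68 to -0.07. Of 8 heat shock genes 6 were positive (median 0.22, adjusted p = 0.593, and 0.24 without those arrays), with HSPA8 at 2.35 ± 1.15 and at 0.27 without treated arrays 3 and 5, and HSPA1L at -0.70 ± 0.38 and at -0.42 without them. None of these genes passed over all probes or adjusted over the list alone.

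Over all SK-MEL-28 probes limma called 0, with a smallest adjusted p of 0.537. At an unadjusted p under 0.05 there were 446 probes, 202 higher and 244 lower, where chance gives 398.65. The replicate block raised the unadjusted count to 857. It was 206 without treated arrays 3 and 5, 296 without treated array 3, 228 without treated array 5, and 720 on leaving out treated array 1.

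The 10 SK-MEL-28 genes with the smallest p included PRR14, a tether of heterochromatin to the nuclear lamina, with a log2 change of -1.05 ± 0.19 (SE, adjusted p = 0.537), from 8.76 ± 0.20 (SD, n = 5) in untreated to 7.71 ± 0.31 (SD, n = 5) in treated cells. BRWD1 had -1.16 ± 0.25 (adjusted p = 0.753). The others, each at an adjusted p of 0.838, were CXXC5 at -1.77 ± 0.40, the homeobox gene SHOX2 at -1.43 ± 0.33, NEURL2 at -1.12 ± 0.26, the junction protein gene PLEKHA7 at -1.41 ± 0.35, TPGS2 at 1.49 ± 0.36, the small GTPase RRAS at 1.15 ± 0.29, the transcription termination factor PCF11 at 0.90 ± 0.22 (untreated array 2 at 8.44, the other untreated arrays at 7.64 to 7.79) and ZNF516-DT at 0.86 ± 0.21. The treated arrays lay on the same side of the untreated mean in 5 of 5 cases for each of the 10 genes. Because the genes were chosen by small p on these arrays, this and their kept direction add no further support. Without treated arrays 3 and 5 all 10 kept their direction, with PRR14 at -0.93, CXXC5 at -1.61 and PLEKHA7 at -0.93 (-0.83 with the replicate block as well). By scan brightness CXXC5 had -3.15 within the 4 brighter arrays and -0.85 within the 6 dimmer ones, and NEURL2 had -0.68 within the brighter arrays.

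The treatment effect was not shown to differ between the lines for any gene. Over 5321 probes the contrast of both effects called 0 by limma (smallest adjusted p = 0.595), with 291 at an unadjusted p under 0.05, where chance gives 266.05. The Mia-PaCa-2 effect was the lower one for 264 of these 291, and the median difference over all probes was -0.22. The arrays that resembled both lines may account for this one-sidedness. The median log2 level of the probes was 7.17 on the untreated Mia-PaCa-2 pair and 6.60 on that line's other arrays. On the treated SK-MEL-28 pair it was 7.16, against 7.02. The split and the median difference are not given without these arrays, so no one-sided difference of the lines was shown. The count was 157 without the 4 arrays that resembled both lines, 437 without SK-MEL-28 treated array 1, and 434 with the replicate block. The genes with the smallest p were TPGS2, with a difference (Mia-PaCa-2 effect minus SK-MEL-28 effect) of -1.67 ± 0.36 (SE) on the log2 scale, N4BP2L2 at -2.04 ± 0.47, the RNA-binding protein gene RBM7 at -1.42 ± 0.37, the integrin subunits ITGA3 at -1.0 ± 0.26 and ITGB4 at -1.37 ± 0.39, MUC1 at -1.50 ± 0.40, the leukotriene receptor CYSLTR2 at -1.05 ± 0.28, the signalling suppressor SOCS6 at -1.31 ± 0.36, RRAGC, a Rag GTPase of amino acid sensing, at -1.41 ± 0.39 and DTD1 at -1.18 ± 0.33. Their adjusted p ran from 0.595 to 0.629, and without the 4 arrays all kept their sign, which is likely for genes chosen by small p. The differences were then -0.71 for ITGB4, -0.96 for MUC1, -0.64 for ITGA3, -0.78 for DTD1, -0.72 for CYSLTR2, -1.16 for RBM7, -1.42 for TPGS2, -1.33 for RRAGC, -1.21 for SOCS6 and -2.03 for N4BP2L2. None of 15 lists differed by camera (smallest adjusted p = 0.0969, and 0.367 with an estimated correlation, with 4 lists at an unadjusted p under 0.05), including glycolysis and hypoxia (5 genes, median difference -0.66), ribosomal proteins (18 genes, -0.82) and proteasome (11 genes, -0.42, adjusted p = 0.462). Without the 4 arrays none of 15 lists differed either (smallest adjusted p = 0.153, and 0.287 with an estimated correlation), and these medians were -0.18, 0.35 and -0.09, so the ribosomal difference changed sign.

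Across the 5321 shared probes the changes of both lines correlated with Pearson's r of 0.319 and Spearman's rho of 0.355, and 62.7% had the same sign. Probes are not independent replicates, and leaving out each array in turn gave a jackknife SE of 0.187. Without the 4 arrays that resembled both lines r was 0.00459. Leaving out SK-MEL-28 treated array 3 alone gave 0.206, and array weights gave 0.136.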

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

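Chosen only after the result had been seen were the tests of another line's label, of the array surface and of target from both lines, all tests of gene lists without the 4 arrays named here (except the count over splits), the test of probe level for the DNA replication and oxidative phosphorylation lists, and the test of scan brightness.

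Untreated arrays 4 and 5 of Mia-PaCa-2 and treated arrays 3 and 5 of SK-MEL-28 resembled both lines. The tables argue against another line's label, since the own line's profile kept a weight of at least 0.467 on each of the 4 (0.374 before normalization), and against the normalization, since the other line's profile had a weight of at least 0.417 before it. A run of array rows read from the other line is also argued against, because in all 25 bands of rows the lower correlation exceeded that between the profiles by at least 0.146. The rows were taken from the probe numbers, on the assumption that these encode row and column. Each band spans all columns, so columns or scattered spots read from the other line would not show there and stay open. Target of both lines on 1 array may be the source and stays open. The sum of both profiles raised the correlation by at least 0.112 over the better single profile, against at most 0.000488 on the other 18 arrays. On 1 of the 4 arrays it reached 0.895, under the limit of 0.9 set for the test. That shortfall decides nothing, since untreated array 3 and treated array 1 of SK-MEL-28, which resembled their own line, reached 0.896 and 0.886. Some levels on the 4 arrays lay above those of both lines, higher than the fitted weights would give. Ribosomal protein probes had medians of 12.02 and 12.07 on the 2 pairs, against 11.56 and 7.76 on the other Mia-PaCa-2 and SK-MEL-28 arrays. Proteasome probes had 10.30 and 10.10, against 9.93 and 8.84. Splicing probes, UBE2N and PSMD12 lay between the lines. How the normalization acts on such a sum was not tested, so these levels do not decide it. No biological explanation was tested.

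In Mia-PaCa-2 the G2/M, DNA replication and oxidative phosphorylation lists were higher and the glycolysis and hypoxia list lower in treated cells by camera at the preset correlation, and none of them passed with an estimated correlation (adjusted p = 0.766 for G2/M and glycolysis and 0.822 for the others). Among 10000 level-matched random lists the G2/M, DNA replication and glycolysis medians lay at percentiles 100, 99.99 and 0, which argues against a trend of the change with probe level for these, but the oxidative phosphorylation median lay at percentile 85.07, so such a trend is not excluded there. The random genes were drawn independently, whereas the estimated correlations in the G2/M, DNA replication and glycolysis lists were 0.305, 0.385 and 0.139. Random medians therefore spread too little, and these percentiles overstate how far the lists stand out. The untreated arrays that also carry the SK-MEL-28 profile may account for much of the G2/M, DNA replication and oxidative phosphorylation shifts, whose medians without them were 0.126, 0.0151 and 0.0541, while the glycolysis median was -0.36 and passed at the preset correlation (adjusted p = 0.0441) but not with an estimated one (0.71). Chance was not excluded for the number of lists, since 23 of 100 splits of the 12 arrays, the real one included, gave at least the real 4 lists (highest other 7), and without those arrays 63 of 100 gave at least 2 (highest other 8). An effect of the treatment on glycolysis genes was not shown by these arrays and stays open, and testing it would take new arrays that each resemble 1 line.

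In SK-MEL-28 the ribosomal protein list had a median change of 0.63 but did not pass (adjusted p = 0.0521), lying above the untreated mean on 3 of 5 treated arrays (1 of 3 without treated arrays 3 and 5). Medians of 0.85 within the 4 brighter arrays and 0.47 within the 6 dimmer ones decide nothing about scan brightness, because each set holds one of treated arrays 3 and 5 and as many treated as untreated arrays. Treated arrays 3 and 5, which also carry the Mia-PaCa-2 profile, may account for the shift, as the median was -0.29 without them. For the 0 lists called the splits decide nothing, since any split reaches 0 (all 100 did, highest other 6). Without these arrays the list did not pass (adjusted p = 0.715), also with the replicate block (median -0.00, adjusted p = 0.942), and an effect of the treatment on it was not shown.

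Chance was not excluded for the counts of probes at an unadjusted p under 0.05. All counts of splits and relabellings include the real grouping. The counts of 0 past the adjusted threshold cannot be tested by splits, because all 100 reach 0 in each case (highest other 37 in Mia-PaCa-2, 1719 in SK-MEL-28 and 26 for the difference between the lines). In Mia-PaCa-2 7 of 100 splits gave at least 1113 probes (highest other 2685). The highest split had both arrays resembling both lines on the same side, and the median count was 719.5 where they stood together and 130 where they stood apart. In SK-MEL-28 28 of 100 splits gave at least 446 probes (highest other 2912). That highest split set the 4 brighter arrays and treated array 5 against the rest, so it also had both arrays resembling both lines on the same side. It points to a structure of the arrays, and the splits do not say which of these it follows. The median count was 410 where those arrays stood together and 123 where they stood apart, and with brightness as a block the real count was 756. With the pairs as a block, 1 of 16 splits that part all pairs gave at least 857 probes, and this was the real grouping itself (highest other 727). At least 1 list came from 8 of 16 (highest other 3), and these splits are too few for a share under 0.05. For the difference between the lines 30 of 100 relabellings without regard to pairs gave at least 291 probes (highest other 1298), as did 13 of 100 that kept the SK-MEL-28 pairs apart (highest other 930), a count added later with its prediction written before its outcome. With the replicate block 22 of 100 relabellings within the pairs of both lines gave at least the 434 probes of that fit (highest other 1054). For the correlation of both lines' changes 21 of 100 gave one at least as far from 0 as 0.319 (highest other 0.441), and likewise 21 of 100 with the SK-MEL-28 pairs kept apart (highest other 0.440). The 4 arrays that resembled both lines may account for this correlation, which was 0.00459 without them. Lying on the untreated side in Mia-PaCa-2 and the treated side in SK-MEL-28, they shift both changes toward the same difference of the line profiles.

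The 184 sets of arrays tested for outliers covered array measures, gene lists and named genes. In 6 of them, all of named genes, a single array lay far from the others of its group, where chance gives about 1 in 20, or 9.2. The test looks for 1 array apart, so 2 arrays that deviate together can hide each other. It could not flag the pairs that resembled both lines, and its count does not argue against outlying arrays. On the log2 scale, ATF3 stood at 4.84 on treated array 2 of Mia-PaCa-2 (others 5.52 to 5.83) and UBQLN1 at -0.61 on untreated array 5 (others 5.21 to 5.84). NDUFA6 stood at 9.39 on treated array 4 of Mia-PaCa-2 (others 8.41 to 8.73) and UBE2N at 12.20 on treated array 5 (others 11.58 to 11.80). In SK-MEL-28 PCF11 stood at 8.44 on untreated array 2 (others 7.64 to 7.79) and RPS16 at 8.17 on untreated array 5 (others 5.40 to 5.94).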

How the results depend on the processing

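The fits without the 4 arrays that resembled both lines, those by scan brightness and those at an estimated correlation with the block or with 1 array left out were the tests chosen only after the result had been seen. Quantile normalization, median centring and the intensity trend changed no count of calls. In Mia-PaCa-2 1 probe passed with array weights and 1 with all 22 arrays in 1 fit, both N4BP2L2, and the cause was not tested. Against 4 lists with all arrays, 2 passed with array weights (G2/M and glycolysis), 0 with an estimated correlation, 2 without the 4 arrays (glycolysis and, newly, the unfolded protein response) and 0 without them at an estimated correlation. Leaving out 1 array gave 2 to 6 lists. In SK-MEL-28 1 list, the ribosomal one, passed without the lowest 25% of probes, with complete probes only, with array weights, with the per-sample files, with the mean of all probes of a gene, with the replicate block, with the brightness block and within the dimmer arrays. Within the brighter arrays 3 passed, and leaving out 1 array gave 0 to 2. With an estimated correlation 0 lists passed in either line whichever array was left out. With the replicate block at an estimated correlation 0 passed. The cause was not tested for any of these.

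With the replicate block, which pairs the SK-MEL-28 arrays, the count of probes stayed at 0 in both lines and for the difference, with 857, 1207 and 434 at an unadjusted p under 0.05 in SK-MEL-28, Mia-PaCa-2 and the difference, and no call other than the ribosomal list changed. Beside limma's 0, Welch's test per probe also called 0 in both lines, with 858 probes at an unadjusted p under 0.05 in Mia-PaCa-2 and 361 in SK-MEL-28. The unadjusted Mia-PaCa-2 count was 590 with all 22 arrays in 1 fit, where 5321 probes were tested in place of 11604, and 643 to 1887 on leaving out 1 array. For the difference it was 177 without the lowest 25% of probes, where fewer probes were tested.

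Without the 4 arrays the correlation of both lines' changes was 0.00459 against 0.319, and with array weights it was 0.136. The SK-MEL-28 ribosomal list turned to -0.29, also at an estimated correlation, and the difference of that list between the lines from -0.82 to 0.35. RPS16 turned to -0.20, RPS2 to -0.30, PSMD8 to -0.0717 (-0.0594 with the block), UBE2N to -0.36 (-0.29) and UBE2T to -0.0303 (-0.30). These arrays held the highest treated values, as the levels given for RPS2 and UBE2N show, and for the others the cause was not tested. Of 913 alternative values for 81 entries, each a named gene in 1 comparison, 905 kept direction and call, 8 turned, and none of 1016 left-out values turned. These genes were chosen by small p on the same arrays and none passed in the main fits, so a kept sign and call says little. The count also ignores size. HSPA8 in SK-MEL-28 counts as kept, with 2.35 over all arrays and 0.27 at its lowest. The number of arrays, and missing values among the lowest and brightest probes, limit what these arrays show.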

Other observations

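The fits without the 4 arrays, the estimated correlation with 1 array left out, the levels compared across lines and the look at the N4BP2L2 probe were tests chosen only after the result had been seen. In Mia-PaCa-2, genes of the unfolded protein response and of ATF4 signalling did not pass with all arrays and passed without untreated arrays 4 and 5. Of 18 such genes 12 had positive changes with a median of 0.30 on the log2 scale (camera, adjusted p = 0.231), and without those arrays the median was 0.23 (adjusted p = 0.0441, and 0.71 with an estimated correlation). CHAC1, which degrades glutathione, passed adjusted over the list alone (limma, adjusted p = 0.00636) and no gene passed over all probes. The bZIP factor CEBPG had 0.59 ± 0.23 (SE), XBP1, a transcription factor of the unfolded protein response, 0.66 ± 0.29 and the stress-induced factor ATF3 0.50 ± 0.22, and without those arrays they had 0.37, 0.66 and 0.62. The mixed test of fry had an adjusted p of 0.00812 and its directional test 0.351, and the list lay above the untreated mean on 4 of 6 treated arrays, with and without those untreated arrays in it. Among heat shock genes the ubiquitin-binding UBQLN1 had 1.42 ± 0.83, with untreated array 5 at -0.61 and a change of 0.42 without that array, and the small heat shock protein gene HSPB8 -0.28 ± 0.20 (0.38 and -0.17 without untreated arrays 4 and 5).

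Other lists in Mia-PaCa-2 did not pass by camera with all arrays. Tubulin and dynein genes had a median of 0.23 (20 genes, adjusted p = 0.101), 0.34 without untreated array 2, where they passed (adjusted p = 0.0292, and 0.436 with an estimated correlation), and 0.08 without untreated arrays 4 and 5. Ribosomal protein genes had -0.06 (49 genes, 34 negative, adjusted p = 0.246) and -0.21 without untreated array 1, where they passed (adjusted p = 0.00234, and 0.753 with an estimated correlation), and 0.02 without untreated arrays 4 and 5. Epithelial and pancreas markers had -0.36 (9 genes, adjusted p = 0.164), with the tight junction gene CLDN4 at -0.36 ± 0.17 and MUC1 as the member passing adjusted over the list alone (limma, adjusted p = 0.00950), and -0.26 without those arrays. The medians were -0.26 for coagulation and serine protease genes (adjusted p = 0.246), 0.09 for mRNA splicing (0.456), -0.08 for the interferon response (0.509), 0.08 for autophagy and lysosome (0.624), 0.02 for NRF2 targets (0.624) and 0.16 for cholesterol synthesis (0.624). Without untreated arrays 4 and 5 these were -0.33, -0.03, -0.09, 0.04, -0.08 and 0.07 in the same order. They were 0.09 for NF-kB targets (0.664), 0.03 for tRNA synthetases (0.841), 0.02 for core histones (0.849) and -0.07 for immediate early genes (0.849), and without those arrays -0.10, -0.18, -0.05 and -0.01. For NRF2 targets, NF-kB targets, tRNA synthetases, core histones and immediate early genes the median and the test differ in sign. Blood cell, fibroblast and melanocyte markers had too few measured genes to test, with 1, 1 and 3.

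In SK-MEL-28 the other lists did not pass by camera either. NRF2 targets had a median of 0.43 (6 genes, adjusted p = 0.343, above the untreated mean on 5 of 5 treated arrays, or 3 of 3 without arrays 3 and 5) and 0.30 without treated arrays 3 and 5, and autophagy and lysosome genes 0.67 (5 genes, adjusted p = 0.420) and 0.17 without them. At an adjusted p of 0.593 stood apoptosis-promoting genes (-0.15), the unfolded protein response (0.21), immediate early genes (0.22), oxidative phosphorylation (0.09), epithelial markers (0.57), tubulin and dynein (0.29) and deubiquitinases (0.07). Without treated arrays 3 and 5 these medians were -0.24, -0.07, 0.20, -0.12, -0.04, 0.09 and 0.10 in the same order. DNA replication had 0.28 and glycolysis and hypoxia 0.07 (both 0.594), p53 targets -0.01 (0.814) and NF-kB targets -0.04 (0.907), with camera pointing the other way for the last pair. Without those arrays the medians were -0.18, -0.09, -0.22 and 0.03. Too few genes were measured for apoptosis-inhibiting genes (2), blood cell markers (3), cholesterol synthesis (2), coagulation (1), core histones (3), fibroblast markers (4), the interferon response (2), melanocyte markers (1) and tRNA synthetases (3).

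Probes of ribosomal proteins and of UBE2N had lower values on the 8 SK-MEL-28 arrays that resembled their own line than the same probes had on treated arrays 3 and 5. The lines were normalized separately, so these levels were not tested against each other. Ribosomal protein probes measured in both lines (15) had a median log2 level of 7.76 on the 8 SK-MEL-28 arrays that resembled their own line, 11.56 on the 10 such Mia-PaCa-2 arrays, 12.07 on treated arrays 3 and 5 of SK-MEL-28 and 12.02 on untreated arrays 4 and 5 of Mia-PaCa-2. Over all 5195 probes these medians were 7.02, 6.60, 7.16 and 7.17. Proteasome probes (12) had 8.84, 9.93, 10.10 and 10.30 in the same order. UBE2N stood at 5.76 ± 0.46 (SD, n = 8) on those SK-MEL-28 arrays, at 11.63 ± 0.28 (SD, n = 10) on those Mia-PaCa-2 arrays, and at 10.37 and 10.57 on treated arrays 3 and 5. GAPDH stood at 11.57 ± 0.81 (SD, n = 8) and 11.59 ± 1.03 (SD, n = 10) on the same sets of arrays, with 12.71 and 13.50 on treated arrays 3 and 5. PSMD12 stood at 12.45 ± 0.69 (SD, n = 8) and 10.24 ± 0.86 (SD, n = 10), with 11.16 and 11.48 on those arrays. Whether the probe names or the target of those 8 SK-MEL-28 arrays hold was not settled, and this limits every gene and list named for that line.

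One N4BP2L2 probe had the smallest p in Mia-PaCa-2, with a log2 change of -2.13 ± 0.32 (SE, limma adjusted p = 0.120). Treated values were 3.34 to 4.77 (5 arrays) and untreated values 5.48 to 7.02. It passed with array weights (adjusted p = 0.0457) and with all 22 arrays in 1 fit (0.00777), and without untreated arrays 4 and 5 it had -1.80 (0.884). The other 3 probes of the gene had 0.47, 0.42 and -0.07, and in SK-MEL-28 the same probe had -0.09.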
